A study of Mus musculus with 7 samples.

How the data were processed

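The series holds RNA-seq of 7 libraries of regulatory T (Treg) cells, purified by fluorescence-activated cell sorting from total lung digests of mice carrying the R576 allele of the IL-4 receptor alpha chain and an EGFP reporter of Foxp3. Per the labels, 3 libraries come from Foxp3-EGFP+ CCR6+ cells and 4 from Foxp3-EGFP+ CCR6– cells. The female mice, 5 to 7 weeks old, were injected with 100 µg of ovalbumin, boosted 2 weeks later, exposed from day 29 to an aerosol of 1% ovalbumin for 30 min a day on 3 days, and killed on day 32. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, cDNA was made with a SMART-Seq v4 ultra low input kit and libraries with a KAPA Hyper Prep kit. Neither kit is described there as marking the strand.

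The deposited values are a signal per gene symbol: read counts that the authors divided by a size factor of each library. That reading rests on the deposited values, which are whole multiples of a step in each library, within 0.001 reads for 100% of the values. Per the submitters' processing notes, STAR 2.5.1b, HTSeq 0.6.1p1, DESeq2 1.6.3 and the mm10 build are listed, with no role or order. The gene annotation, the filters and the use of strand in counting are not given in the sources used here. Each file lists 19736 gene symbols, 27 of which read as dates, and 2 symbols have more than 1 entry. Of the symbols, 97.0% were found among the gene names of the reference tables. Division by the step gave the whole reads behind each value, from 11607780 to 47261246 reads per library. In CCR6+ replicate 2, the shallowest library, 1 read is worth 2.27 units of the deposited scale, against 0.677 units in CCR6– replicate 4.

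Genes with a value of at least 10 in at least 3 of the 7 libraries were kept, which left 14582 genes. They were tested with limma 3.58.1 under R 4.3.3 on log2(value + 1), two-sided, with no covariate and with Benjamini-Hochberg adjustment over the genes kept at 0.05. All log2 differences are CCR6+ minus CCR6– on this scale, which understates the change of low genes. They are given with the standard error (SE) from limma, and levels are given as mean ± SD of the deposited values. A total of 22 gene lists, 13 programs and 9 sets of cell type markers, was fixed before the data were examined and tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, with Ccr6 left out of each list. Camera with an estimated correlation and fry were run beside it. For 6 genes, among them Ccr6, Foxp3, Il4ra, Il17a and Il17f, an exact permutation test of the absolute difference of the group means of log2(value + 1) used all 35 splits of the libraries (scipy 1.17.1), with adjustment over the 6 genes. Its smallest possible p is 0.0286.

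The genes to name were set by a rule made before the data were examined. It takes those 6 genes, then up to 10 genes per direction past the adjusted threshold, with groups that do not overlap and a mean of at least 50. As no gene passed, the 10 genes of smallest p per direction took that place, with the same 2 conditions on overlap and mean and without unnamed transcripts. Date-like symbols were left out as well, which was decided after the data were seen. It also takes up to 4 members of smallest p per list, the members past adjustment over the list alone up to 8, and for marker lists the 2 members of highest mean. Some items under this rule are not reported here. The text summarises others by their list, and the values under other settings cover every gene of the rule. Positions are those of GENCODE mouse release 21 on mm10, 1-based. Reads of a gene and of its antisense partner, or of near-identical copies, may not have been separable.

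The alternatives were other pseudocounts (0.5 and 8), no filter, a filter on a mean of at least 100, equal library totals, TMM scaling, quantile normalization, limma-trend with robust moderation, arrayWeights, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Chosen after the data were seen were edgeR and DESeq2 without CCR6+ replicate 2, the mean of the epithelial and the endothelial and stromal lists as a covariate, and the log2 RPM in olfactory and vomeronasal receptor genes as a covariate. The tests were tested on simulated counts for 14083 genes with the same group sizes and 50 changed genes at each of 4 fold changes. Limma recovered 0 of the 50 genes changed 2-fold, 22 changed 4-fold, 26 changed 8-fold and 27 changed 16-fold, with 8 false calls among 83. EdgeR recovered 6, 29, 34 and 29 with 6 false calls among 104. DESeq2 recovered 16, 36, 40 and 37 with 69 false calls among 198. The share of false calls lay above the threshold of 0.05 for limma as well, and far above it for DESeq2. Of all changed genes, 187 passed the filter, so some of each 50 may not have been tested. The counts were drawn with dispersions estimated by edgeR and without an outlying library. Camera called 7 of 200 unchanged sets and 100 of 100 shifted sets at an unadjusted 0.05. The simulated genes were drawn independently of each other and the sets at random. This check thus does not cover lists whose members move together, such as the B cell list, with an estimated correlation of 0.818.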

Results

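The transcriptome of lung Treg cells was profiled in 7 libraries, 3 of CCR6+ and 4 of CCR6– cells, all Foxp3-EGFP+ and from allergen-challenged mice with the R576 form of the IL-4 receptor alpha chain. CCR6 is the receptor of the chemokine CCL20. The recovered reads came to 35182288, 11607780 and 27520975 in CCR6+ replicates 1 to 3, and to 31083571, 35405497, 31443528 and 47261246 in CCR6– replicates 1 to 4. CCR6+ replicate 2 stood apart. It had the fewest reads and yet only 2.16% of the genes at 0, against 6.89% to 29.7% in the other libraries. The mean of its epithelial list lay 4.41 above the median of the other 6 libraries on the log2 scale, that of its endothelial and stromal list 5.15 above, and that of its macrophage and monocyte list 2.73 above, whereas its Treg identity list lay at -1.06. The first principal component, with 71.6% of the variance, placed it at 254 and the other libraries between -161 and 95.5. Each library was counted as 1 sample. No pair of libraries agreed within the noise of read sampling, which does not show that they came from separate mice or cells.

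**Figure D1:**
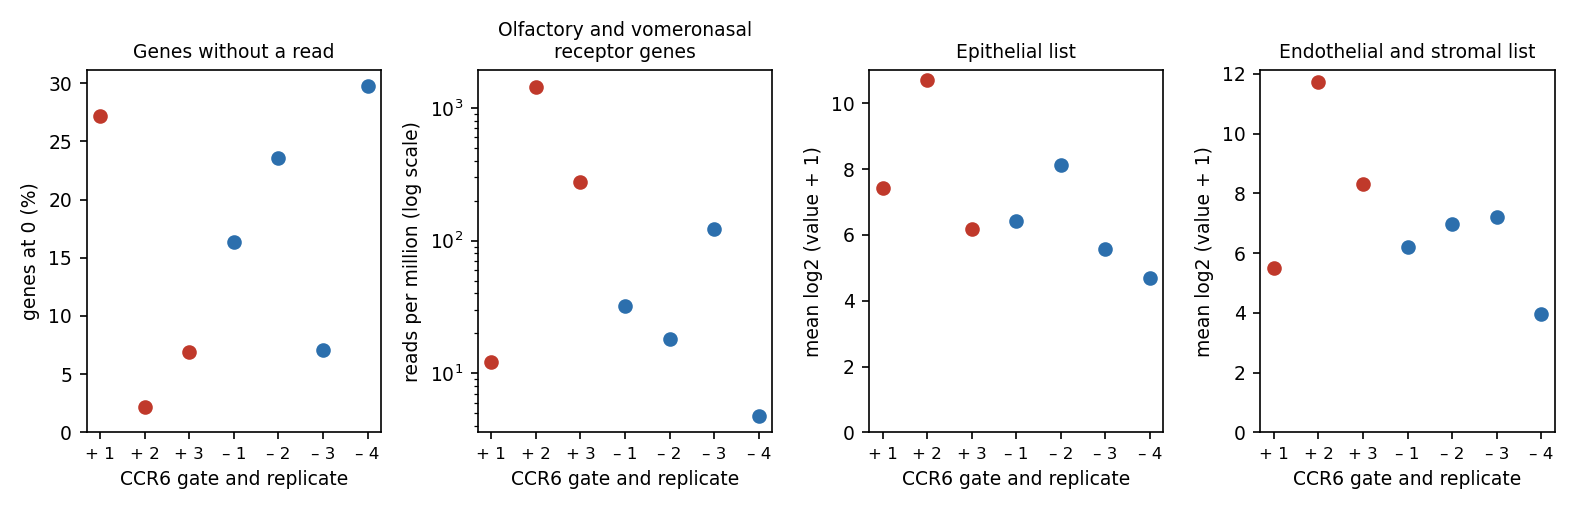
Library measures per replicate, with CCR6+ in red and CCR6– in blue: percent of genes at 0, RPM (reads scaled to library size) in olfactory and vomeronasal receptor genes on a log axis, and the mean log2 (value + 1) of the epithelial and the endothelial and stromal lists. CCR6+ replicate 2 has the lowest share of genes at 0, 2.16%, and the highest value in the other panels.

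The sorted markers were read first, as a check of the labels. Ccr6 was higher in CCR6+ cells, at 5488 ± 2414 normalised counts (n = 3) against 617 ± 312 (n = 4), a log2 difference of 3.19 (SE 0.56), and the groups did not overlap (exact permutation test, two-sided, p = 0.0286, adjusted over 6 genes 0.0429). Foxp3, the Treg transcription factor whose reporter was sorted on in both groups, stood at 33447 ± 19614 and 31384 ± 8699 (exact permutation p = 0.857). Il4ra, the receptor chain that carries the R576 allele, stood at 26093 ± 12134 and 24579 ± 3244 (exact permutation p = 1.0). The log2 differences of Foxp3 and Il4ra, -0.09 and -0.01, change sign in several settings, among them quantile normalization and the fit without CCR6+ replicate 2, so no direction is given for them. The genes whose positions are given here are annotated as protein coding. Ccr6, with 8 exons, lies on mm10 chromosome 17 from 8236043 to 8257141, Foxp3 on chromosome X from 7573644 to 7595245 and Il4ra on chromosome 7 from 125552120 to 125579474. Of the exonic bases of Foxp3, 31.5% overlap other annotated genes, some of them antisense.

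The comparison of CCR6+ with CCR6– cells asks, after the title of the series, whether the CCR6+ fraction carries a program like that of TH17 helper cells. The cytokine genes Il17a and Il17f rose from 6.29 ± 3.71 to 43.7 ± 39.0 and from 6.98 ± 3.02 to 107 ± 103, each with no overlap between CCR6+ (n = 3) and CCR6– libraries (n = 4) and an exact permutation p of 0.0286, the smallest this design allows (adjusted over 6 genes 0.0429). Of the 21 tested members of the TH17 list, 9 rose and none fell when p was adjusted over the list alone, and 0 passed over all genes. Among these 9, Il23r, the receptor subunit for IL-23, went from 3.45 ± 4.00 to 238 ± 43, Il1r1, an IL-1 receptor, from 130 ± 46 to 1028 ± 585, and Ahr, the aryl hydrocarbon receptor, from 1615 ± 117 to 4539 ± 994. Il17re, a subunit of the receptor for IL-17C, went from 16.3 ± 21.1 to 415 ± 407. Ccl20, the ligand of CCR6, went from 2.28 ± 4.56 to 25.0 ± 13.6 and is listed at 0 in 3 of the CCR6– libraries. The list was shifted upwards by camera (adjusted p = 1.04e-06), and this call held with an estimated correlation (adjusted p = 0.0455) and by fry (adjusted p = 0.000364). The median log2 difference of its members was 2.12, and 1.33 without CCR6+ replicate 2, whose own mean for this list lay 2.46 above the median of the other 6 libraries. Without that library the log2 differences of Il17a, Il17f and Il17re were 1.73, 2.52 and 4.34, against 2.40, 3.31 and 5.10 with it. With quantile normalization those of Il17a, Il17f and Ccl20 were 0.23, 1.51 and 1.43, against 3.71 for Ccl20 without it. Sox13, Zbtb16 and Kit, known from gamma-delta T cells or innate lymphoid cells, had log2 differences of 2.95, 3.75 and 2.48, or 1.57, 2.12 and 1.55 without CCR6+ replicate 2, and did not pass. They were among the members of smallest p in the list of CD8, NK, gamma-delta and innate lymphoid markers. In that list 8 members were positive and 4 negative, with a median of 0.63, or 0.019 without CCR6+ replicate 2. Kit is also in the list of eosinophils, neutrophils and mast cells. With CCR6– replicate 4 left out the number of TH17 members past adjustment over the list alone fell to 4. Il17a lies on chromosome 1 from 20730905 to 20734496, Il17f on chromosome 1 from 20777146 to 20790617, Il23r on chromosome 6 from 67422932 to 67491855 and Il1r1 on chromosome 1 from 40225080 to 40317257.

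**Figure D2:**
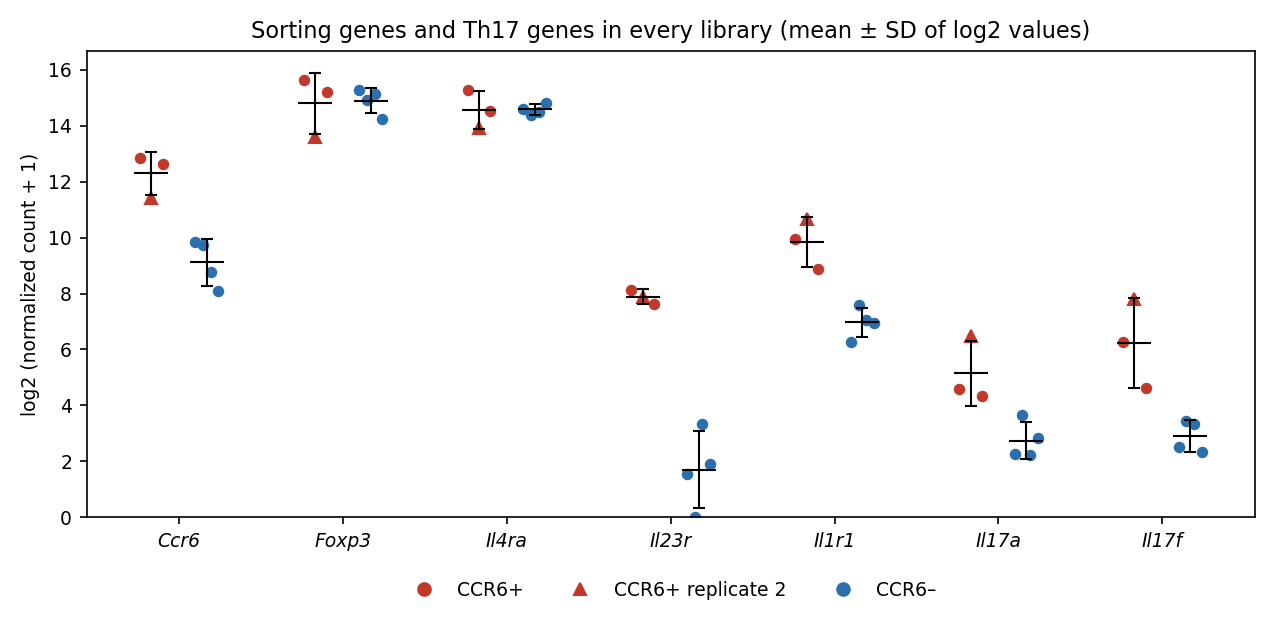
Log2 (normalized count + 1) of 7 genes in each library, with the mean and SD of each group in black. Ccr6, Il23r, Il1r1, Il17a and Il17f do not overlap between the groups, while Foxp3 and Il4ra do.

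Some genes of naive and recirculating T cells were lower in CCR6+ cells. Of the 16 tested members of that list, 13 had negative and 3 positive log2 differences. With p adjusted over the list alone, 5 fell and 0 rose, and 0 passed over all genes. Ccr7, a chemokine receptor for lymph node entry, fell from 35702 ± 15235 to 13139 ± 3879. The transcription factor genes Satb1 and Lef1 fell from 21163 ± 4259 to 8536 ± 856 and from 12892 ± 2605 to 6654 ± 481, and S1pr1, a receptor for exit from lymph nodes, from 28008 ± 2247 to 19688 ± 1716. Camera called the list (adjusted p = 3.4e-06), as did fry (adjusted p = 0.0365), but the adjusted p with an estimated correlation was 0.257. The count of 5 members became 3 with equal library totals and 2 with quantile normalization. It also became 2 with CCR6+ replicate 1 left out and 3 with CCR6– replicate 4 left out. The median log2 difference of the list was -0.53, and -0.98 without CCR6+ replicate 2. In that library the list mean was not lower, at 0.14 above the median of the others. The means of CCR6+ replicates 1 and 3, 11.15 and 11.6, were the lowest.

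All 20 members of the proliferation list had negative log2 differences, and for 13 of them the groups did not overlap. Over all genes tested this held for 13.5% in either direction, where a random grouping gives 5.71% on average. The members move together (estimated correlation 0.404), so they are not independent draws. The median log2 difference of the list was -0.56, and -0.40 without CCR6+ replicate 2. Rrm2, a subunit of ribonucleotide reductase, stood at 6861 ± 1015 against 12338 ± 2019, and the replication licensing genes Mcm3 and Mcm5 at 6042 ± 930 against 9346 ± 819 and 6236 ± 1029 against 9721 ± 1124. No member passed adjustment over the list alone, where the smallest adjusted p was 0.0582. The list was shifted downwards by camera (adjusted p = 1.56e-10), but not with an estimated correlation (adjusted p = 0.285) or by fry (adjusted p = 0.0734).

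The effector and tissue Treg list was shifted upwards by camera (adjusted p = 0.0456), with 18 of 22 members positive, 0 past adjustment over the list alone and an adjusted p = 0.611 with an estimated correlation. Havcr2, which encodes the inhibitory receptor TIM-3, stood at 951 ± 343 against 302 ± 99. This call ended without CCR6+ replicate 1, where the direction turned (adjusted p = 0.909), without CCR6+ replicate 3 (adjusted p = 0.202) and without CCR6– replicate 1 (adjusted p = 0.0983). It also ended with a pseudocount of 8, no filter, TMM scaling, DESeq2 and fry, and the adjusted p was 3.79e-06 without CCR6+ replicate 2. The follicular helper list was shifted upwards by camera (adjusted p = 0.0129) and by fry (adjusted p = 0.00694), with an adjusted p = 0.257 under an estimated correlation. Its member Tox2, a transcription factor gene, rose from 847 ± 156 to 2577 ± 774 as the only 1 of 12 past adjustment over the list alone. The call of this list ended without CCR6+ replicate 1 (adjusted p = 0.14), without CCR6+ replicate 3 (adjusted p = 0.0503) and with no filter (adjusted p = 0.093). The 15 B cell markers had a median log2 difference of 2.23, or 1.70 without CCR6+ replicate 2, and the 17 macrophage and monocyte markers one of 2.16, or 1.24. Whether either moved with the follicular helper list over the libraries was not tested. In CCR6+ replicate 2 the mean of the follicular helper list was the highest, 1.195 above the median of the others.

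The Treg identity list did not pass (camera adjusted p = 0.187), with 8 of its 21 members positive and 13 negative. Gpr83, a receptor gene enriched in Treg cells, stood at 3168 ± 1607 in CCR6+ and 14404 ± 7166 in CCR6– cells, and Entpd1 and Nt5e, for the ectoenzymes CD39 and CD73, at 2915 ± 359 against 2238 ± 156 and 8199 ± 2961 against 4867 ± 560. Camera shifted the list downwards without CCR6+ replicate 1 (adjusted p = 0.00451) and with no filter (adjusted p = 0.0199), but upwards without CCR6+ replicate 2 (adjusted p = 0.0163). The TH2 list did not pass (adjusted p = 0.161), though Hpgds, a prostaglandin D2 synthase, went from 49.7 ± 14.6 to 142 ± 27.5 and was the only 1 of 12 members past adjustment over the list alone, a difference whose sign turns with quantile normalization. Without CCR6+ replicate 2 this list passed upwards (adjusted p = 0.00264), as did that of chemokine and migration receptors (adjusted p = 0.0118, against 0.982 with all libraries). With all libraries the TH2 list passed upwards under the lung marker covariate (adjusted p = 0.000913) and the receptor background covariate (adjusted p = 0.00533). The chemokine and migration receptor list did so under the lung marker covariate (adjusted p = 0.0473). Camera called neither the TH1 list (adjusted p = 0.468), that of TCR activation and immediate early genes (adjusted p = 0.695), that of IL-4 receptor, IL-6, STAT3 and GRB2-MAPK signalling (adjusted p = 0.229), that of TGF-beta signalling (adjusted p = 0.76) nor that of glycolysis and hypoxia (adjusted p = 0.127). Their median log2 differences were -0.022, -0.015, -0.052, 0.20 and -0.18, while the means of the lists of TCR activation, IL-4 receptor signalling and glycolysis were positive, at 0.14, 0.16 and 0.055. Without CCR6+ replicate 1 the lists of IL-4 receptor signalling (adjusted p = 0.0163) and glycolysis (adjusted p = 0.00451) were shifted downwards, as they were with no filter. Glycolysis was also shifted downwards with arrayWeights (adjusted p = 0.0445).

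**Figure D3:**
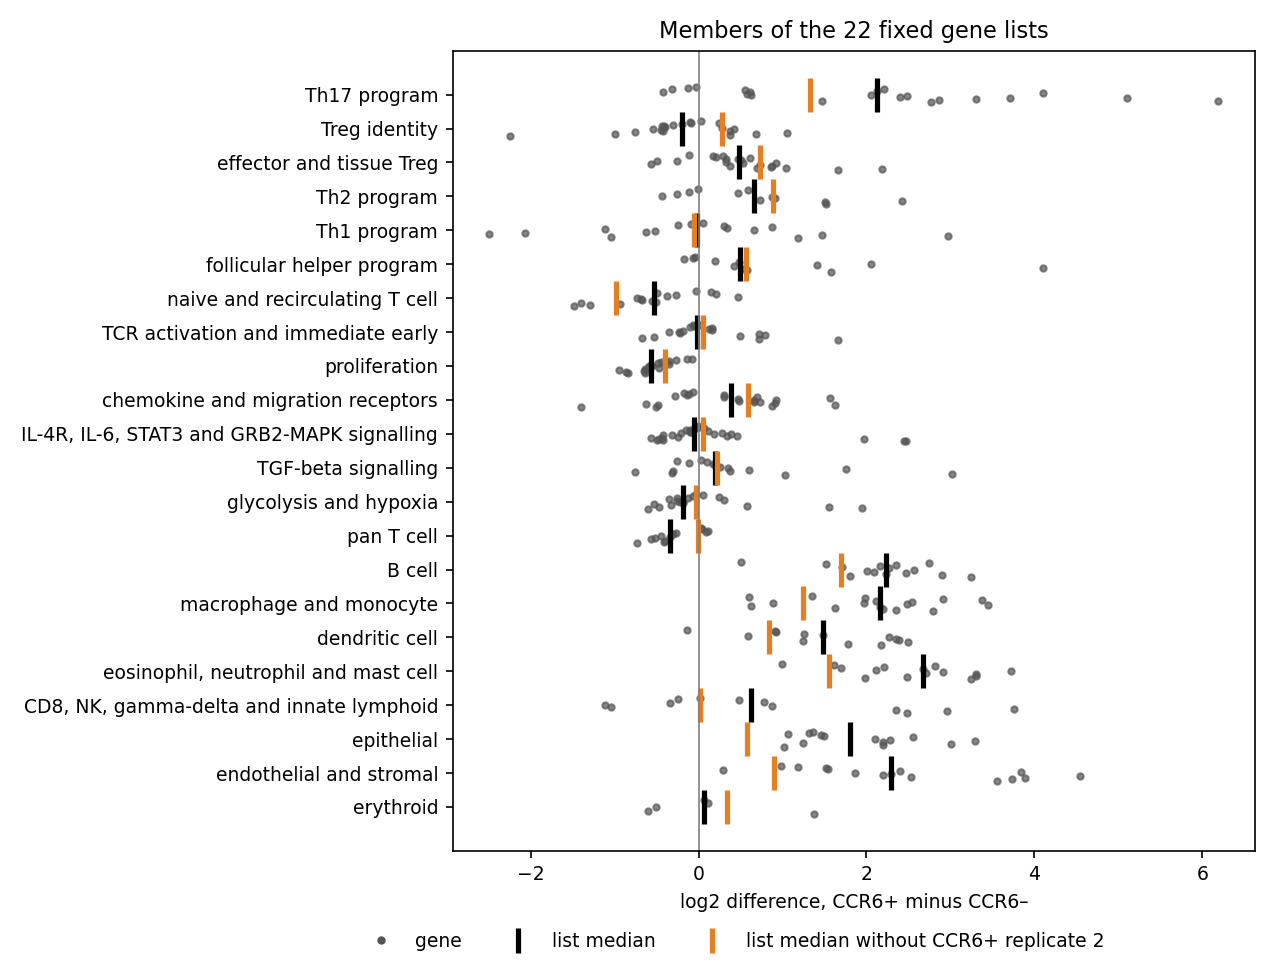
Log2 difference between CCR6+ and CCR6– libraries for each member of the 22 gene lists, with the list median over all libraries in black and without CCR6+ replicate 2 in orange. The TH17 median is 2.12 and 1.33, the proliferation median -0.56 and -0.40, and the epithelial median 1.80 and 0.58.

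Several lists of markers of other cell types were shifted upwards in the CCR6+ group, by camera at its preset correlation only. All members had positive log2 differences in the lists of B cells (15), macrophages (17), eosinophils, neutrophils and mast cells (15), epithelium (14) and endothelium and stroma (15), as did 12 of 13 dendritic cell markers, and 0 passed adjustment over their list alone. Camera called those of B cells (adjusted p = 0.000109), macrophages and monocytes (adjusted p = 0.000401), dendritic cells (adjusted p = 0.00231), eosinophils, neutrophils and mast cells (adjusted p = 0.000196), epithelium (adjusted p = 0.00793) and endothelium and stroma (adjusted p = 0.00465) upwards and that of pan T cell genes downwards (adjusted p = 0.00983), each with an adjusted p = 0.611 under an estimated correlation and none by fry. Without CCR6+ replicate 2 the epithelial and the endothelial and stromal lists no longer passed (adjusted p = 0.104 each), nor did the pan T cell list (adjusted p = 0.984), while the B cell list (adjusted p = 0.00031), the macrophage list (adjusted p = 0.00264), the dendritic cell list (adjusted p = 0.00243) and the list of eosinophils, neutrophils and mast cells (adjusted p = 0.00178) did. Those calls used the preset correlation. In each of the lists still called, the mean of a remaining CCR6+ library lay below that of CCR6– replicate 1, so the groups overlapped. Lyz2 stood at 27731 ± 30670 in CCR6+ against 6017 ± 5755 in CCR6– libraries, Cd74 at 26693 ± 26058 against 5097 ± 3255 and Sftpc, a surfactant gene, at 14160 ± 22466 against 1780 ± 1484, none of which passed. Without CCR6+ replicate 2 the log2 differences of Lyz2, Cd74 and Sftpc went from 2.49, 2.09 and 1.49 to 1.59, 1.29 and -0.20. The list of CD8, NK, gamma-delta and innate lymphoid markers (adjusted p = 0.586) and the erythroid list (adjusted p = 0.743, with a test directed downwards and a median of 0.062) did not pass.

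Over all 14582 genes, limma called 0 genes higher and 0 lower, with 1540 at an unadjusted p under 0.05, of which 1198 were higher and 342 lower. EdgeR on the recovered reads called 2 genes, both higher and Postn among them, and DESeq2 called 543 higher and 136 lower, with no adjusted p for 1095 genes. Of the 543, 492 had their highest value in CCR6+ replicate 2, and without that library DESeq2 called 102 higher and 79 lower. The groups did not overlap for 1160 genes higher and 806 lower, 13.5% of the genes, where a random grouping gives 5.71% on average. Genes are not independent, and this share was not computed for other splits of the libraries, so the excess was not tested. Of the genes of smallest p, which did not pass, Postn, for the matrix protein periostin, stood at 4136 ± 644 against 402 ± 112 (limma adjusted p = 0.0625, edgeR adjusted p = 0.0114), Rnase4, a secreted ribonuclease, at 2132 ± 130 against 727 ± 99, Nr1d1, the clock gene for REV-ERBα, at 1144 ± 200 against 134 ± 48, Hlf, a PAR bZIP transcription factor gene, at 469 ± 139 against 84.4 ± 18.1 and Ctsl, for the protease cathepsin L, at 4958 ± 771 against 1323 ± 331. Klrb1f, a member of a gene family with similar copies, stood at 484 ± 43 against 130 ± 33 and Rab11fip5 at 127 ± 34 against 32.4 ± 6.3. In the other direction St8sia6, a sialyltransferase gene, stood at 2388 ± 263 in CCR6+ and 7242 ± 865 in CCR6– cells, Wnt3 at 95.4 ± 33.9 and 384 ± 91, Gata1, a transcription factor gene, at 184 ± 93 and 817 ± 241, Smc6, for a chromosome maintenance protein, at 9838 ± 1152 and 22293 ± 4168 and Ms4a4b, again one of a family of similar copies, at 15100 ± 3001 and 30006 ± 3245. Sh3bgrl2, Slc35g1 and BC094916 had log2 differences of -0.94, -1.05 and -0.77. Of the exonic bases of Ctsl, 26.8% overlap other annotated genes, as do 13.4% of those of Rnase4, 13.7% of Lef1, 9.51% of Il4ra and 8.55% of Nr1d1. Postn lies on chromosome 3 from 54361109 to 54391037 and St8sia6 on chromosome 2 from 13651021 to 13794064.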

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

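Among 145 sets of values of the 4 CCR6– libraries, covering the named genes, the list means, the depth and the share of genes at 0, 6 held a library far from the other 3, where chance gives about 5% of such sets. The 3 CCR6+ libraries were too few for this test. No test here was chosen after its result was seen, and no explanation was tested for these 6. In CCR6– replicate 4, Lck, a T cell kinase gene, stood at 97710 normalised counts, against 44520 to 48330 in the other CCR6– libraries, and Lat, an adaptor of T cell receptor signalling, at 39160 against 16210 to 18270. In CCR6– replicate 1, Mgl2, a lectin gene of dendritic cells and macrophages, stood at 145.7 against 35.87 to 43.92, and the mean log2 value of the effector and tissue Treg list at 10.59 against 10.77 to 10.8. In CCR6– replicate 2, the mean of the proliferation list stood at 12.06 against 11.6 to 11.67, and Ccl20 at 9.115 where the other 3 libraries are listed at 0.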

How the results depend on the processing

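The covariates and the fits of edgeR and DESeq2 without CCR6+ replicate 2 were chosen after the data were seen. The TH17 list kept its direction and its call in every setting run, with adjusted p from 2.65e-18 to 0.0455, and the lists of proliferation and of naive and recirculating genes kept theirs in all but those named here. Depth limits the low genes: 3 reads correspond to 6.82 units in CCR6+ replicate 2 and 2.03 in CCR6– replicate 4, so Il23r, Il17a, Il17f and Ccl20 in CCR6– cells lie near that floor. The cause of the changes listed here was not tested. Of the 121 named genes tested, over 23 settings, 2464 values kept their direction and side of the threshold, 175 came to pass it in the same direction and 102 changed sign.

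Genes higher and lower by limma, 0 and 0, became 1 and 0 with a pseudocount of 0.5 or TMM scaling, 2 and 0 with a pseudocount of 8, a mean of at least 100, edgeR or edgeR without CCR6+ replicate 2, 2 and 2 with quantile normalization, 8 and 2 with limma-trend, 1458 and 1028 with arrayWeights, 543 and 136 with DESeq2 and 102 and 79 with DESeq2 without CCR6+ replicate 2. They stayed at 0 and 0 in all 7 fits that leave out a library, with 1005 to 3398 genes at an unadjusted p under 0.05, and under both covariates. ArrayWeights did not converge and gave CCR6+ replicate 3 a weight of 24.18. DESeq2 made 679 calls with all libraries and 181 without CCR6+ replicate 2, and 123 genes were shared, all in the same direction. Quantile normalization moved the median log2 difference of all genes by -0.178 and split the calls at an unadjusted p under 0.05 into 679 higher and 830 lower, against 1198 and 342. The median moved by 0.333 with no filter, by -0.135 with a mean of at least 100 and by -0.114 with the receptor background covariate.

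The replicate numbers 1 to 3 occur in both groups. The deviations of same-numbered libraries from their group means correlated at -0.128, -0.112 and 0.342, and only CCR6+ replicate 3 correlated best with its own number. A pairing by number was thus not seen. The group means include CCR6+ replicate 2, which stands apart, so these correlations cannot decide whether same-numbered libraries share a mouse. The replicate block left 0 genes higher and 0 lower and 12 lists, and the naive and recirculating list had 3 members past adjustment over the list alone.

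The 12 lists past camera became 1 with an estimated correlation and 3 with fry. The TH17 members past adjustment over the list alone, 9, became 14 with arrayWeights and 4 to 9 over the fits that leave out a library. The naive and recirculating members, 5, became 3 with equal library totals, 2 with quantile normalization or the lung marker covariate, 10 with arrayWeights or DESeq2 without CCR6+ replicate 2, and 2 to 7 over the fits that leave out a library. For the list of effector and tissue Treg genes the adjusted p was 0.0699 with a pseudocount of 8, 0.2 with no filter, 0.0555 with TMM scaling, 0.0597 with DESeq2, 0.611 with an estimated correlation, 0.196 with fry and 3.79e-06 to 0.909 over the fits that leave out a library. For follicular helper genes it was 0.093 with no filter, 0.257 with an estimated correlation and 0.00243 to 0.14 over those fits. For naive and recirculating genes it was 0.257 and for proliferation 0.285 with an estimated correlation, and 0.0734 for proliferation with fry. With arrayWeights the calls ended for the lists of B cells (0.298), macrophages (0.903), dendritic cells (0.539), epithelium (0.903) and pan T cell genes (0.903), while the erythroid list passed downwards (0.0218). The pan T cell call also ended with a mean of at least 100 (0.061), quantile normalization (0.613), the lung marker covariate (0.999), the receptor background covariate (0.596) and, without CCR6+ replicate 2, edgeR (0.921) and DESeq2 (0.863). With the lung marker covariate the calls ended for dendritic cells (0.0879) and for epithelium and endothelium, whose markers make up that covariate (0.855 each), with the receptor background covariate for endothelium (0.514), and with DESeq2 without CCR6+ replicate 2 for epithelium (0.0628). The log2 difference of Ccr6 passed at 3.35 with arrayWeights, 3.15 with DESeq2 and 3.49 with DESeq2 without CCR6+ replicate 2.

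With quantile normalization, the log2 difference became 0.10 for Foxp3, 0.18 for Il4ra, -0.17 for Ebi3, -0.053 for Hpgds, -0.047 for Clec10a, -0.12 for Gzma, -1.31 for Alas2, -1.79 for Hbb-bt and -2.46 for Hbb-bs, and the direction turned, at adjusted p = 0.836 for the list of Treg identity, 0.306 for the list of TCR activation and immediate early, 0.159 for the list of IL-4R, IL-6, STAT3 and GRB2-MAPK signalling and 0.613 for the list of CD8, NK, gamma-delta and innate lymphoid. With arrayWeights, the log2 difference became 0.063 for Foxp3, 0.088 for Lck, -2.45 for Chil3, -0.47 for Cd24a, -0.60 for Sftpa1, -0.095 for Pecam1, -1.92 for Alas2, -1.75 for Hbb-bt and -2.70 for Hbb-bs, and the direction turned, at adjusted p = 0.518 for the list of Treg identity and 0.842 for the list of CD8, NK, gamma-delta and innate lymphoid. With the lung marker covariate, the log2 difference became 0.40 for Foxp3, 0.44 for Il4ra, 0.094 for Lck, -0.47 for Chil3, -0.058 for Gzma, -0.48 for Sftpc, -0.59 for Sftpa1, -0.15 for Pecam1, -1.73 for Col3a1, -0.46 for Hbb-bt and -0.86 for Hbb-bs, and the direction turned, at adjusted p = 0.0473 for the list of Treg identity, 0.286 for the list of TCR activation and immediate early, 0.278 for the list of IL-4R, IL-6, STAT3 and GRB2-MAPK signalling, 0.999 for the list of glycolysis and hypoxia and 0.726 for the list of CD8, NK, gamma-delta and innate lymphoid. With the receptor background covariate, the log2 difference became 0.26 for Foxp3, 0.41 for Il4ra, -0.064 for Pecam1, -1.48 for Col3a1, 0.42 for Hba-a1 and 0.71 for Hba-a2, and the direction turned, at adjusted p = 0.11 for the list of Treg identity, 0.596 for the list of TCR activation and immediate early, 0.334 for the list of IL-4R, IL-6, STAT3 and GRB2-MAPK signalling, 0.596 for the list of glycolysis and hypoxia and 0.596 for the list of erythroid. With edgeR without CCR6+ replicate 2, the log2 difference became 0.49 for Foxp3, 0.35 for Il4ra, -0.078 for Gzma, -0.59 for Sftpc, -0.56 for Sftpa1, -0.096 for Pecam1, -0.32 for Col3a1, 0.11 for Hba-a1 and 0.17 for Hba-a2, and the direction turned, at adjusted p = 0.00346 for the list of Treg identity, 0.82 for the list of TCR activation and immediate early, 0.493 for the list of IL-4R, IL-6, STAT3 and GRB2-MAPK signalling, 0.921 for the list of glycolysis and hypoxia and 0.847 for the list of erythroid. With DESeq2 without CCR6+ replicate 2, the log2 difference became 0.50 for Foxp3, 0.37 for Il4ra, -0.057 for Gzma, -0.56 for Sftpc, -0.54 for Sftpa1, -0.077 for Pecam1, -0.30 for Col3a1, 0.13 for Hba-a1 and 0.19 for Hba-a2, and the direction turned, at adjusted p = 0.00329 for the list of Treg identity, 0.863 for the list of TCR activation and immediate early, 0.374 for the list of IL-4R, IL-6, STAT3 and GRB2-MAPK signalling, 0.863 for the list of glycolysis and hypoxia, 0.863 for the list of CD8, NK, gamma-delta and innate lymphoid and 0.863 for the list of erythroid. With a mean of at least 100, the direction turned, at adjusted p = 0.869 for the list of Th1 program and 0.869 for the list of TCR activation and immediate early. With fry, the direction turned, at adjusted p = 0.909 for the list of Th1 program, 0.863 for the list of TCR activation and immediate early and 0.973 for the list of erythroid. With the replicate block, the log2 difference became 0.073 for Il4ra, -0.15 for Cd3e, -0.20 for Alas2, -0.85 for Hbb-bt and -1.30 for Hbb-bs, and the direction turned, at adjusted p = 0.951 for the list of TCR activation and immediate early and 0.759 for the list of chemokine and migration receptors. With a pseudocount of 8, the log2 difference became -0.018 for Hbb-bt and -0.065 for Hbb-bs, and the direction turned, at adjusted p = 0.917 for the list of chemokine and migration receptors. With no filter, the direction turned, at adjusted p = 0.439 for the list of chemokine and migration receptors and 0.683 for the list of TGF-beta signalling. With equal library totals, the log2 difference became 0.078 for Il4ra, and the direction turned, at adjusted p = 0.985 for the list of chemokine and migration receptors. With DESeq2, the log2 difference became 0.089 for Foxp3, 0.081 for Il4ra, -0.13 for Gzma, -0.25 for Hbb-bt and -0.36 for Hbb-bs, and the direction turned, at adjusted p = 0.813 for the list of chemokine and migration receptors. With edgeR, the log2 difference became 0.048 for Foxp3, 0.032 for Il4ra, -0.20 for Gzma, -0.28 for Hbb-bt and -0.38 for Hbb-bs. With TMM scaling, the log2 difference became -0.055 for Cd3e, -0.067 for Gzma and -0.013 for Hbb-bs.

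Over the 7 fits that leave out a library, the log2 difference changed sign for Foxp3 (-0.51 to 0.52), Il4ra (-0.36 to 0.31), Cd3e (-0.16 to 0.37), Gzma (-0.20 to 0.36), Sftpc (-0.20 to 2.35), Sftpa1 (-0.27 to 2.66), Pecam1 (-0.088 to 0.51), Col3a1 (-0.58 to 3.53), Alas2 (-0.20 to 2.75), Hba-a1 (-2.34 to 0.77), Hba-a2 (-1.54 to 0.60), Hbb-bt (-1.14 to 1.17) and Hbb-bs (-1.49 to 1.35). The direction of these lists turned in at least 1 such fit, with adjusted p of 0.00451 to 0.288 for Treg identity, 3.79e-06 to 0.909 for effector and tissue Treg, 0.28 to 0.923 for TCR activation and immediate early, 0.0118 to 0.889 for chemokine and migration receptors, 0.0163 to 0.602 for IL-4R, IL-6, STAT3 and GRB2-MAPK signalling, 0.143 to 0.888 for TGF-beta signalling, 0.00451 to 0.936 for glycolysis and hypoxia and 0.201 to 0.936 for erythroid.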

Other observations

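Tests chosen only after the result was seen were those of depth and of lung RNA in CCR6+ replicate 2, the bounds for the TH17 list and for Nr1d1 and Hlf without that library, a fit that was itself planned, each value with the receptor background taken off, and the bootstrap interval for the clock genes. The lung marker covariate was also added after the data were seen, as were the receptor background covariate and the fits of edgeR and DESeq2 without CCR6+ replicate 2.

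Clock genes were mixed. Per3 stood at 93.6, 864 and 288 in CCR6+ replicates 1, 2 and 3 and at 56.0 ± 29.5 in CCR6– libraries (n = 4), a log2 difference of 2.521, or 1.725 without CCR6+ replicate 2. Nr1d2 stood at 3409 ± 1299 in CCR6+ (n = 3) and 2059 ± 269 in CCR6– libraries (n = 4), whereas Dbp stood at 237 ± 72 and 284 ± 120 and Arntl at 2456 ± 595 and 2216 ± 577. None of them passed with limma. These genes were chosen after Nr1d1 and Hlf had been seen.

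CCR6+ replicate 2 stands apart from the other 6 libraries. Its lower depth is argued against as the whole reason, since fewer reads leave more genes at 0, yet this library, with the fewest reads, had 2.158% of genes at 0, against 6.891% to 29.73% in the others. The epithelial, endothelial and macrophage lists all lay well above the median of the other libraries, by 2.727 or more, and by 2.73 or more after the read rate of olfactory and vomeronasal receptor genes was taken off, so RNA or cells of other lung cell types may be part of it. Reads from genomic DNA stay open as well: 88.99% of those receptor genes, which lung T cells should not express, had a read at equal depth, against at most 59.29% elsewhere, but a share cannot exceed 100%, so the bound set beforehand, over 2 times the next library, could not be reached, and reads followed exonic length only weakly across these genes (Spearman rho 0.10, genes not being independent replicates). Spread evenly over exons, that rate would account for 3.69% of the reads of this library and leave at most 0.406% of genes at 0, where 2.01% were.

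The TH17 list is higher in CCR6+ libraries. The library that stands apart is argued against as the whole reason, as the list kept a camera adjusted p of 1.86e-08 without it. With the lung marker covariate it was 1.81e-11, in a range of 2.65e-18 to 0.0455 over all settings. That covariate holds epithelial, endothelial and stromal markers only and is highest in CCR6+ replicate 2. It holds no markers of B cells, macrophages, dendritic cells or granulocytes, so it cannot account for admixed RNA of those cells. What stays open is that gamma-delta T cells or innate lymphoid cells may have been in the CCR6+ gate, which the sort on Foxp3-EGFP should have removed. No T cell receptor gamma or delta gene was examined. Of the fixed list of CD8, NK, gamma-delta and innate lymphoid markers, 12 of 16 members were found, none of them such a receptor gene. The 7 detected markers of those written down for these cells (Sox13, Cd163l1, 5830411N06Rik, Zbtb16, Kit, Ncr1 and Il22, 5 of them also in a fixed list and 6 with a mean of at least 10 in CCR6– cells) had a median log2 difference of 2.955 (bootstrap 95% interval 1.94 to 4.34), and of 1.57 (0.56 to 3.20) without CCR6+ replicate 2. With all libraries the lower limit lay above the bound set beforehand, the outcome written down for such cells. That outcome cannot tell them from other admixed cells. Sox13, Zbtb16 and Kit were highest in CCR6+ replicate 2, at 1085, 594 and 6349, where markers of other lung cells were high too. Kit is also a member of the mast cell list. Without CCR6+ replicate 2 the interval included the bound. Both intervals resample the markers, not the libraries, so they do not measure the spread between libraries. In CCR6+ replicates 1 and 3, Sox13 stood at 45.5 and 79.2 (CCR6– libraries 10.4 to 29.4), Cd163l1 at 76.5 and 97.4 (0 to 25.7), 5830411N06Rik at 127 and 95.4 (1.84 to 24.9) and Kit, the most abundant, at 630 and 1341 (176 to 611), these 4 of the 7 being higher in all 3 CCR6+ than in all 4 CCR6– libraries, whereas Ncr1 stood at 107 and 109.6 (57.9 to 217), Zbtb16 at 6.01 and 54.8 (0 to 26.5) and Il22 at 0 and 2.03 (0 to 0.920), and a TH17-like state of the Treg cells themselves remains the untested biological alternative.

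Nr1d1 and Hlf are higher in CCR6+ libraries. Without CCR6+ replicate 2 the smaller of the 2 log2 differences was 2.215, so the difference did not rest on that library alone. Both genes were named because their groups did not overlap in these 7 libraries, which largely fixed this outcome. It is thus no independent evidence against admixed lung RNA, and it says nothing on such RNA in the other CCR6+ libraries. A different time of day of collection stays open: the median log2 difference of 5 clock output genes exceeded that of 4 genes of opposite phase by 0.1229 (bootstrap 95% interval -1.209 to 1.974), and by -0.02235 (-0.9635 to 1.272) without CCR6+ replicate 2, where the sign turns, and each interval spans both bounds set beforehand, 0.5 and 1. Both intervals resample the genes, not the libraries. The output genes ran from -0.2203 to 2.521 and those of opposite phase, expected to be lower, from 0.1056 to 1.821. Cells of another type in the gate, and reads of Thra, which overlaps Nr1d1 on the other strand, were not tested for these genes, so a difference of the CCR6+ cells themselves remains a hypothesis, found on the same 7 libraries.

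All 35 splits of the libraries into 3 and 4 were refitted. The camera p of the TH17 list was smallest for the real split, at 9.411e-08 against 5.909e-07 at best elsewhere. That is 1 split of 35, or 2.86%, the smallest share that these splits can give. It lies under 0.05 for this list alone, without adjustment over the lists or the other counts, so chance is not excluded. For the limma count the splits decide nothing, since the real count is 0 and 35 of 35 splits give at least that, the highest other 131. Chance is not excluded for the other counts either. With DESeq2, 4 of 35 gave at least the real 679, the highest other 1640, and with camera, 8 of 35 gave at least the real 12 lists, the highest other 16. The split with 1640 DESeq2 calls and 131 limma calls sets CCR6+ replicates 2 and 3 and CCR6– replicate 3 against the rest. These are the 3 libraries with the most reads in olfactory and vomeronasal receptor genes, at 1444, 278 and 123 RPM against 4.78 to 32.1 in the others, which points to a structure of the samples other than the CCR6 gate. A split of CCR6+ replicate 1 and CCR6– replicates 2 and 4, the 3 libraries with the fewest such reads, gave 1346 DESeq2 calls.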
